A study of Rattus norvegicus with 24 samples.

How the data were processed

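Liver messenger RNA was profiled in 24 adult female Sprague-Dawley rats of the F2 generation, 1 array per sample, by the labels. The grandfathers (F0) had eaten chow or a high-fat diet (HFD), and the females themselves ate chow or an HFD (42 or 45% of energy from fat, as the labels give it) for 12 weeks. The lines are called the chow line and the HFD line after the grandfather's diet. The groups held 7 chow-line females on chow, 6 chow-line females on the HFD, 6 HFD-line females on chow and 5 HFD-line females on the HFD. Per the labels' protocols, total RNA was extracted with a kit for lipid-rich tissue, and 200 ng was turned into sense-strand cDNA, fragmented, biotin-labelled and hybridised to an Affymetrix whole-transcript array. The growth protocol speaks of gonadal white adipose tissue, while every sample title, source and tissue label says liver; the samples were taken as liver. Arrays are named by the number in the sample title, and no number occurs in more than 1 group. The labels tie no female to a litter, a parent or a grandfather, so each array was treated as an independent animal, and related females would make the p-values too small.

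The authors deposited 1 linear intensity per probe set and array, made with Affymetrix Expression Console and PLIER per the submitters' processing notes. The version, the background correction and the normalization options are not given in the sources used here. The deposited intensities had medians of 97.9 to 128 per array and upper quartiles of 370 to 532, so the arrays had not been brought to 1 common distribution. No 2 columns were identical. For arrays, the number of samples limits the precision.

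From the deposited intensity, log2(value + 16) was computed, with no further normalization in the primary setting, and the 25% of the 20917 probe sets with the lowest mean were left out (mean log2 under 5.72, 5230 probe sets). The remaining 15687 probe sets were fitted in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend) with 4 group means over all 24 arrays. All fold changes are therefore on the log2(value + 16) scale, which understates the change of dim probe sets. Adjusted p-values are limma's two-sided p-values with Benjamini-Hochberg adjustment over the 15687 probe sets, and the threshold was 0.05. The ± after a log2 fold change is its standard error.

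The contrasts were own diet (HFD minus chow) in each line, grandpaternal diet (HFD line minus chow line) on each own diet, the interaction of the 2 diets, and the average effect of each diet over the other. Gene names came from the platform annotation, updated through Entrez identifiers with a RefSeq gene table. Of all probe sets, 18197 had 1 gene (18052 of them matched in that table), 960 had several and 1760 had no name here. Genome coordinates were not used here, because the sources used here name no build.

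There were 34 gene lists, chosen for liver metabolism, stress and immune responses, growth and imprinting, sex bias, and cell types that liver tissue can hold or carry over. List members that were not on a single-gene probe set are not analysed here. Each gene was represented by its probe set with the highest mean (12745 genes). The lists were tested with camera in limma at a preset correlation between genes of 0.01, again with the correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. The fry results are not given below. List p-values were adjusted over the 34 lists within a contrast. Member genes were also adjusted over the list alone. A list score per array was the mean over the members of the log2 signal centred on each gene's mean. Scores were compared between 2 groups by an exact two-sided permutation test, and for the interaction and the averaged grandpaternal effect by 100000 two-sided permutations of the line within each own diet.

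The genes named for each contrast were the 10 largest rises and the 10 largest falls past the threshold among probe sets with 1 gene symbol not starting with LOC or RGD. Where none passed in a direction, up to 3 with the smallest p were taken and are given as not passing. Up to 4 members with the smallest p were named from each list described. The contrasts, lists, naming rule and most alternative settings were fixed before the data were examined.

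The alternatives were quantile normalization, centring each array on its median, no filter or a filter on the lower 50%, offsets of 1 and 50, eBayes without the trend or with the robust option, array weights, 1 probe set per gene, only the groups compared, arrays 21, 22 and 24 left out together, and each array left out in turn. After seeing the data, the 4 arrays that stood apart (21, 22, 24 and 25) were added as a block, were left out together, and were used as a block with quantile normalization. The fit was tested on simulated data with 200 of 15687 probe sets changed, in 10 draws. A change of 1 on the log2 scale was recovered for 96.3% of changed probe sets for own diet in either line, 97.1% for grandpaternal diet on chow, 95.9% for grandpaternal diet on the HFD and 86.0% for the interaction. At 0.5 the shares were 66.3% and 56.5% for own diet in the chow and HFD lines, 66.3% and 56.6% for grandpaternal diet on chow and on the HFD, and 18.8% for the interaction. With fewer changed probe sets the adjusted threshold is harder to reach, and recovery in that case was not simulated. Probe sets called although unchanged had a median of 1.5 and a maximum of 5 per draw for own diet in the chow line, but 6.5 and 46 in the HFD line. They had 3.5 and 13 for grandpaternal diet on chow, 4 and 11 on the HFD, and 0.5 and 7 for the interaction. Figures were drawn with matplotlib 3.10.9.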

Results

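Hepatic gene expression was measured in adult female rats that differed in their grandfather's diet and in their own diet. The arrays reported 20917 probe sets, of which 15687 were tested, and 13823 of those carried 1 gene name. The groups held 7 chow-line females on chow, 6 chow-line females on the high-fat diet (HFD), 6 HFD-line females on chow and 5 HFD-line females on the HFD. Median signal per array lay between 97.9 and 128, and log2 signals of any pair of arrays correlated at 0.963 to 0.991. Over the 15687 tested probe sets alone, the mean of the arrays' median log2(value + 16) was 7.96 ± 0.15 (SD, n = 7), 7.96 ± 0.10 (n = 6), 7.96 ± 0.07 (n = 6) and 7.83 ± 0.08 (n = 5) in the order above.

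The first principal component held 19.1% of the variance and followed array brightness (Pearson r = -0.955 with the array median over 24 arrays, a description of the arrays rather than a test). The second, with 13.8%, set 4 arrays apart from the other 20. These were arrays 21 and 25 (chow line, chow), 22 (chow line, HFD) and 24 (HFD line, HFD), and no array of HFD-line females on chow was among them. The 4 arrays had 830 probe sets higher and 1692 lower than the rest at an adjusted p under 0.05. The third component, with 8.44%, leaned by own diet, without a clean separation.

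**Figure D1:**
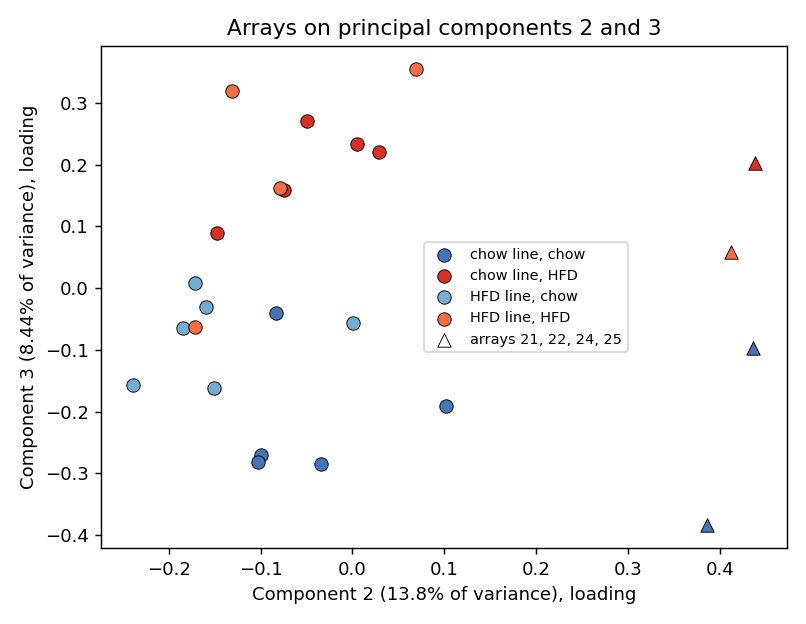
Each point is 1 array, placed by its loadings on principal component 2 (13.8% of variance, horizontal axis) and component 3 (8.44%, vertical axis), coloured by group. The 4 triangles at the right are arrays 21, 22, 24 and 25.

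Own diet in the chow line was compared between 6 females on the HFD and 7 on chow. Genes of cholesterol synthesis fell together on the HFD. Dhcr7, which catalyses the final step of the pathway, went from 11.02 ± 0.23 (SD, n = 7) to 9.74 ± 0.18 (n = 6) in log2 signal, a fold change of -1.28 ± 0.11 (adjusted p = 1.8e-07). Sqle, the squalene epoxidase, fell 3.92-fold (log2 -1.97 ± 0.33, adjusted p = 0.00218) and Idi1, the isopentenyl diphosphate isomerase, fell 3.79-fold (log2 -1.92 ± 0.29, adjusted p = 0.00104). The largest fall of a named gene was in Aacs, which activates acetoacetate for lipid synthesis, at -2.22 ± 0.27 (4.65-fold, adjusted p = 5.76e-05). Marco, a scavenger receptor of macrophages, fell from 7.20 ± 0.25 to 5.90 ± 0.42 (log2 -1.30 ± 0.22, adjusted p = 0.0028).

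In all, 12 probe sets rose and 38 fell in the chow line, which were 12 and 34 genes. After quantile normalization 24 rose and 65 fell (49 of the 50 shared), and after centring 25 rose and 54 fell (49 shared). Vnn1, a pantetheinase induced by PPAR alpha, rose by 1.63 ± 0.29 (3.09-fold, adjusted p = 0.00537). Spink1l, a serine peptidase inhibitor, rose by 1.97 ± 0.34 (adjusted p = 0.00341) and Kcnma1, the pore of the large-conductance potassium channel, by 1.62 ± 0.31 (adjusted p = 0.0117). Fabp2, a fatty acid binding protein (1.35), Nr0b2, a repressor of bile acid synthesis (1.13), Myo3a (1.08), Ccnd1, which encodes cyclin D1 (0.90), Pcdh7 (0.67), Polg2 (0.58) and Synj2 (0.55) rose as well. Among the falls were Mab21l3 (-1.63) and the carbonic anhydrase gene Car12 (-1.61). The remaining falls on the naming rule were in the sterol pathway, namely Acat2 (-1.69 and -1.65 on its probe sets), Hsd17b7 (-1.42) and Mvd (-1.45). Ccnd1, Kcnma1, Nr0b2, Pcdh7, Polg2 and Synj2 each lost the threshold when at least 1 array was left out. Without arrays 21, 22, 24 and 25 the adjusted p was 0.0552 for Fabp2, 0.280 for Ccnd1, 0.135 for Kcnma1, 0.0720 for Nr0b2, 0.267 for Polg2, 0.0520 for Synj2 and 0.186 for the lipid droplet gene Cidea.

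Of the 19 measured members of the cholesterol synthesis and uptake list, 12 fell over all probe sets and 16 fell when adjusted over the list alone, with a median of -0.78 and no member above 0. The list passed camera also with an estimated correlation (adjusted p = 0.00105). Its score fell by 0.94 (exact permutation p = 0.000583, the smallest that 1716 regroupings can give, adjusted p = 0.0198), with all 6 HFD arrays below the chow mean. Stard4, a sterol carrier, fell by 0.76 ± 0.11 (adjusted p = 0.000929). The cholesterol list was the only list whose camera call held with an estimated correlation in this contrast, in the HFD line and in the average of the lines; no list's call held in any of the other contrasts.

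All 14 measured Kupffer cell and macrophage markers were lower on the HFD in the chow line, with a median of -0.44. Marco passed over all probe sets and 11 fell when adjusted over the list alone, among them Cd5l (-0.80), Vsig4 (-0.70) and Clec4f (-0.65). The list passed camera (adjusted p = 3.71e-16) but not with an estimated correlation (adjusted p = 0.12 with an estimated correlation), and its score fell by 0.52 (exact permutation p = 0.0035, adjusted p = 0.0396). The 12 lymphocyte markers had a median of -0.23 with 0 passing over the list alone by limma; camera's adjusted p of 1.28e-05 became adjusted p = 0.292 with an estimated correlation, and Prf1 (-0.40 ± 0.14) had the smallest p. Of the 12 endothelial and 9 stellate cell markers, 0 passed either way, and their medians were -0.04 and -0.06.

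Genes of fatty acid oxidation were higher on the HFD in 22 of 24 cases in the chow line, with a median of 0.23. Vnn1 passed over all probe sets, and 5 rose when adjusted over the list alone, including Decr1 (0.55), Acadl (0.28) and Eci1 (0.61), enzymes of the beta-oxidation of fatty acids. The camera call of this list (adjusted p = 2.6e-08) was lost with an estimated correlation (adjusted p = 0.292 with an estimated correlation). Of 18 genes of fatty acid and triglyceride synthesis, Acss2, the cytosolic acetyl-CoA synthetase, fell by 1.07 ± 0.16 (adjusted p = 0.000929), and adjusted over the list alone Fads2 (0.29) and Thrsp (0.23) rose. Cidea, a lipid droplet protein, fell (-0.94 ± 0.21, adjusted p = 0.0438, a call lost in at least 1 fit with an array left out), while adjusted over the list alone Slc27a2 (0.25) and Fabp4 (0.80) rose and Pparg fell (-0.69) among 18 lipid droplet and fatty acid uptake genes.

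Of the 34 lists, 12 passed camera in the chow line. Phlda2, an imprinted gene that restrains growth, fell by 0.59 ± 0.10 (adjusted p = 0.00186) as the only 1 of 10 imprinted genes to pass. Of 20 cell cycle genes, Ccnd1 rose over all probe sets and Ccnb2 (0.36) joined it over the list alone; the camera call (adjusted p = 0.00273) gave adjusted p = 0.589 with an estimated correlation. All 4 measured male-biased genes were higher (median 0.43), and Cyp3a18 (1.01) and Cyp2a2 (0.30) rose adjusted over the list alone, with adjusted p = 0.12 with an estimated correlation. All 5 female-biased genes were higher as well (median 0.19), and Cyp2a1 (0.24) and Cyp2c7 (0.20) rose over the list alone, with adjusted p = 0.292 with an estimated correlation. Hepatocyte markers had 5 of 13 rising over the list alone, with Alb at 0.20 and Tf at 0.16 (-0.01 after quantile normalization), a median of 0.15 that became 0.01 after quantile normalization, and adjusted p = 0.292 with an estimated correlation. Of 13 immediate early genes, 0 passed over all probe sets and Ier3 (-0.67) and Ier2 (-0.55) fell over the list alone (adjusted p = 0.316 with an estimated correlation). Oxidative phosphorylation (31 genes, median 0.11), lipoproteins (14 genes, 0.14) and the interferon response (23 genes, -0.13) had camera calls with 0 members passing over the list alone by limma, and gave adjusted p = 0.589, 0.589 and 0.636 with an estimated correlation. Lists without a camera call held Gsta3 (-1.08), Cyp3a23-3a1 (1.21), Hlf (0.79), Per2 (0.84), Orm1 (-0.81) and Mthfd1 (-0.37), each passing over its list alone.

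Own diet in the HFD line was compared between 5 females on the HFD and 6 on chow. Genes of the sterol pathway fell in this line as well. Sqle fell 5.38-fold (log2 -2.43 ± 0.35, adjusted p = 0.000902), from 10.47 ± 0.46 (SD, n = 6) to 8.05 ± 0.83 (n = 5), and Idi1 fell 4.52-fold (log2 -2.17 ± 0.32, adjusted p = 0.000902). Dhcr7 fell by 1.35 ± 0.12 (adjusted p = 3.74e-07). Hsd11b1, whose enzyme regenerates active glucocorticoid, fell by 2.21 ± 0.51 (4.64-fold, adjusted p = 0.0353), and Gsta3, a glutathione transferase, fell by 1.40 ± 0.31 (adjusted p = 0.0262). The rises were led by C16h10orf71 (1.90 ± 0.41, adjusted p = 0.0235), Spink1l (1.84 ± 0.37, adjusted p = 0.0147) and Kcnma1 (1.54 ± 0.34, adjusted p = 0.0285).

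In the HFD line, 15 probe sets rose and 103 fell, which were 12 and 90 genes. Tox, a chromatin-binding factor (1.36), Zfp354a (1.01), Or51r1 (0.90), Glt1d1 (0.79), Synj2 (0.54), Aknad1 (0.53) and Tsc22d1 (0.52) also rose. Acat2 (-1.74), Aacs (-1.60), Car12 (-1.54), Mab21l3 (-1.54), Msmo1 (-1.53) and Mvd (-1.39) fell. The split depended on scaling, with 34 rises and 56 falls after quantile normalization (67 of the 118 calls shared) and 25 rises and 73 falls after centring each array on its median (85 shared). Leaving out 1 array gave 56 to 148 calls, with 65 without array 37, 56 without 42, 69 without 24, 72 without 44 and 58 without 45, and the calls of Aknad1, C16h10orf71, Glt1d1, Gsta3, Hsd11b1, Kcnma1, Spink1l, Synj2, Tsc22d1 and Zfp354a were among those lost in at least 1 such fit. Without arrays 21, 22, 24 and 25 the adjusted p was 0.0516 for Mvd, 0.0569 for Or51r1, 0.0542 for Tsc22d1, 0.0861 for Glt1d1, 0.129 for Aknad1, 0.0932 for Gsta3, 0.0885 for Abcc3 and 0.0762 for Marco.

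The cholesterol list had 15 of 19 members falling over all probe sets and all 19 when adjusted over the list alone, with a median of -0.96 and adjusted p = 0.00758 with an estimated correlation. Its score fell by 1.07 (exact permutation p = 0.00216, the smallest that 462 regroupings can give, adjusted p = 0.0368). All 5 HFD arrays were below the chow mean. After centring the adjusted p was 0.0736, the lowest that a lone list at this smallest permutation p can reach. That value is set by the number of lists and shows no weaker fall. The centred score was 0.42 ± 0.16 (SD, n = 6) on chow and -0.53 ± 0.17 (n = 5) on the HFD. Stard4 fell by 0.89 ± 0.12 (adjusted p = 0.000759). All 14 macrophage markers were lower in this line too, with a median of -0.28 (-0.14 after quantile normalization), and Marco passed (-1.03 ± 0.24, adjusted p = 0.0361), the 1 member to do so over all probe sets and over the list alone. The list's camera call gave adjusted p = 0.724 with an estimated correlation. The 24 fatty acid oxidation genes had a median of -0.20, with 3 above 0 and 0 passing over the list alone by limma, and camera's adjusted p was 0.217. Vnn1 was at 0.08 ± 0.32 in this line.

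In the HFD line 11 lists passed camera. Among them were cell cycle (20 genes, median 0.06, adjusted p = 0.00997), oxidative phosphorylation (31 genes, 28 of them lower, median -0.16, and -0.03 after quantile normalization), extracellular matrix (15 genes, median 0.01) and erythroid markers (6 genes, median 0.13), with 0 members passing over the list alone by limma. These gave adjusted p = 0.714, 0.739, 0.724 and 0.714 with an estimated correlation. Single members of other lists passed over all probe sets. Acss2 fell by 0.90 ± 0.18 (adjusted p = 0.0119), Cidea by 1.32 ± 0.23 (adjusted p = 0.00397) and Phlda2 by 0.69 ± 0.11 (adjusted p = 0.000956). Orm1, an acute-phase plasma protein, fell by 0.99 ± 0.22 (adjusted p = 0.0327), Abcc3, an exporter of bile salts and conjugates, by 0.70 ± 0.16 (adjusted p = 0.0327) and Epcam, a surface marker of bile duct cells, by 0.76 ± 0.15 (adjusted p = 0.0139). With quantile normalization the adjusted p was 0.0719 for Abcc3, 0.0924 for Orm1, 0.0708 for Gsta3 and 0.0579 for Hsd11b1, and the calls of Abcc3, Marco and Orm1 were also lost in at least 1 fit with an array left out. Adjusted over the list alone, Psmb8 (-0.59), Psmb9 (-0.49) and Rtp4 (-0.68) fell among 23 interferon genes, Nqo1 (-0.75), Gsr (-0.37) and Gclm (-0.48) among 17 oxidative stress genes, and Slc37a4 (-0.31), Irs1 (-0.45) and Pck1 (-0.56) among 17 genes of glucose metabolism. The camera calls of these lists gave adjusted p = 0.724, 0.714 and 0.714 with an estimated correlation. Per2, a clock repressor, rose over the list alone (1.13) and Gadd45b (-0.96) and Ier3 (-0.55) were among 6 immediate early genes that fell over the list alone, with adjusted p = 0.714 with an estimated correlation for either list. Over the list alone, Pnpla2 (-0.59) and Slc27a5 (-0.42) fell among 18 lipid droplet genes, Abcb4 (-0.57) among 17 bile acid genes, Dnajb1 (-0.48) and Hspb1 (-0.81) among 9 heat shock genes, Mthfd1 (-0.44) and Gnmt (-0.34) among 16 methyl donor genes and Cpa1 (-1.97) among 9 acinar markers, while Pnpla3 (2.18) rose among 18 lipid synthesis genes. These calls used unshifted fold changes, and the median over all probe sets in this contrast was -0.09. After centring each array, the methyl donor score was 0.015 on chow and 0.028 on the HFD, against 0.038 and -0.071 as deposited. The mean lipid droplet, bile acid, heat shock and acinar scores stayed lower on the HFD after centring, each by less than as deposited. The centred bile acid score was 0.07 ± 0.13 (SD, n = 6) on chow and 0.02 ± 0.11 (n = 5) on the HFD, against 0.09 and -0.08 as deposited. The centred acinar score was -0.05 ± 0.11 and -0.10 ± 0.16, against -0.03 and -0.20. Those 2 centred differences were smaller than the SDs. Cpa1 was 9.73 ± 1.78 (SD, n = 5) on the HFD, against 11.70 ± 0.40 (n = 6) on chow.

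The own-diet effects of the lines were set side by side; they share no arrays. Across the 15687 probe sets, which are not independent replicates, the fold changes correlated at Pearson r = 0.304 and Spearman rho = 0.175. Both lines called 4 rises and 31 falls in common, where 0.0115 and 0.25 would be shared by independent lists, and 0 probe sets passed in opposite directions. Among the 133 probe sets called in either line, 119 had the same sign in both and the fold changes correlated at 0.895. These probe sets were picked by the size of the same fold changes, which raises the correlation, so it describes them and is not a test. The lines also share an estimate of the spread per probe set, so their calls are not fully independent lists. Of the 15 called in the chow line alone, 11 had an unadjusted p under 0.05 in the same direction in the HFD line, and of the 83 called in the HFD line alone, 42 did so in the chow line.

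**Figure D2:**
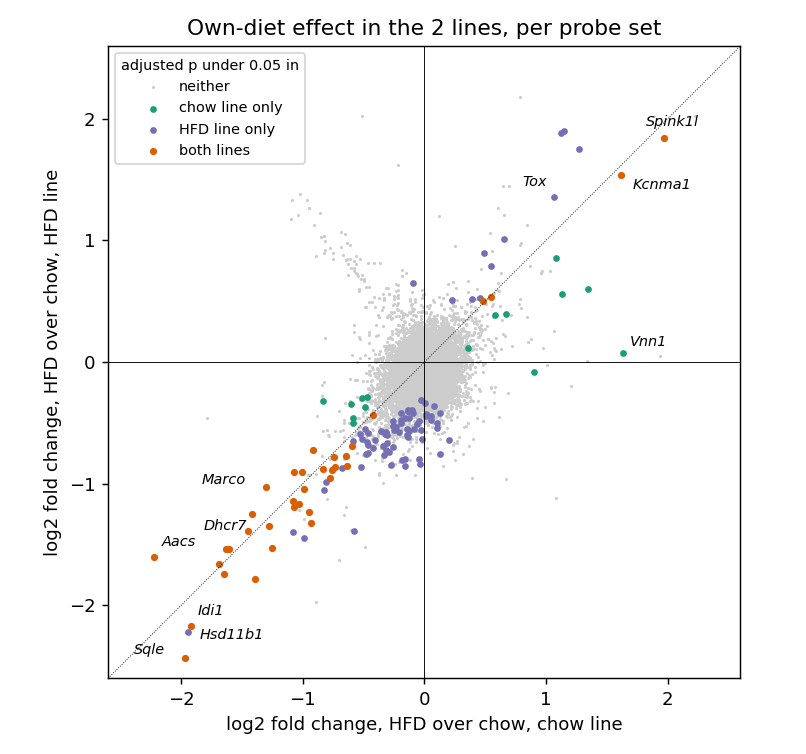
Each point is 1 probe set, with its log2 fold change of HFD over chow in the chow line (horizontal axis) and in the HFD line (vertical axis), coloured by the line in which its adjusted p was under 0.05. The 35 probe sets called in both lines lie near the dotted line of equal change, with Sqle, Idi1, Aacs and Dhcr7 at the lower left, and 0 were called in opposite directions.

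Averaged over the lines, own diet changed 312 probe sets, of which 57 rose and 255 fell (49 and 231 genes). After quantile normalization 167 rose and 260 fell (275 of the 312 shared), and after centring 121 rose and 212 fell (260 shared). Sqle (-2.20 ± 0.24, adjusted p = 1.97e-06), Hsd11b1 (-2.08 ± 0.35, adjusted p = 0.000744), Idi1 (-2.05), Aacs (-1.91), Acat2 (-1.70), Mab21l3 (-1.58), Car12 (-1.58), Mvd (-1.42) and Msmo1 (-1.39) fell, as did Cpa1, a pancreatic carboxypeptidase (-1.43 ± 0.35, adjusted p = 0.0263). Lrtm2 (2.12 ± 0.42, adjusted p = 0.00512), Spink1l (1.91), Kcnma1 (1.58), C16h10orf71 (1.53), Tox (1.22), Per2 (0.99), Fabp2 (0.98), Myo3a (0.97), Vnn1 (0.85) and Dmrta1 (0.85) rose. The average of Vnn1 combined 1.63 in the chow line with 0.08 in the HFD line. Without array 21 the count was 470, and the calls of Cpa1, Dmrta1 and Vnn1 were lost in at least 1 fit with an array left out.

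All 19 cholesterol genes fell in the average, over all probe sets and over the list alone, with a median of -0.87 (adjusted p = 0.000795 with an estimated correlation). Dhcr7 fell by 1.31 ± 0.08 (adjusted p = 9.68e-11) and Stard4 by 0.82 ± 0.08 (adjusted p = 1.73e-06). Marco (-1.16 ± 0.16, adjusted p = 6.93e-05), Cd5l (-0.70 ± 0.14, adjusted p = 0.00731) and Vsig4 (-0.55 ± 0.14, adjusted p = 0.0393) fell among the 14 macrophage markers, and 11, Clec4f (-0.49) included, fell over the list alone; the median was -0.34 and the camera call gave adjusted p = 0.501 with an estimated correlation. Of 24 fatty acid oxidation genes, Vnn1 rose by either adjustment, largely through the chow line. The list had a median of 0.03 and adjusted p = 0.833 with an estimated correlation. In the circadian list of 16, Per2 and Hlf (0.66) rose and Nfil3 (-0.42) fell, over all probe sets and over the list alone, with adjusted p = 0.503 with an estimated correlation. Ier3 (-0.61) and Ier2 (-0.50) fell among 13 immediate early genes, 5 of which fell over the list alone (adjusted p = 0.503 with an estimated correlation). Psmb9 (-0.38) and Psmb8 (-0.44), subunits of the immunoproteasome, were the 2 of 23 interferon genes that fell, by either adjustment (adjusted p = 0.71 with an estimated correlation).

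Lists without a camera call in the average still held genes that passed over all probe sets. Acss2 (-0.99) fell, and over the list alone 4 of 18 fatty acid and triglyceride synthesis genes rose, Dgat2 (0.21) among them, and 3 fell. Cidea (-1.13) and Pparg (-0.63) fell and Fabp4 (0.62) rose, and over the list alone 1 of 18 lipid droplet genes rose and 5 fell. Orm1 (-0.90), the endotoxin co-receptor gene Cd14 (-0.44) and Socs3 (-0.37) fell among 23 acute phase genes, by either adjustment. Gsta3 (-1.24) and Akr7a3 (-0.49) fell among 22 xenobiotic genes (3 over the list alone), Nqo1 (-0.65) and Gsr (-0.28) among 17 oxidative stress genes (3 over the list alone, with Gclm at -0.39), and Phlda2 (-0.64) among 10 imprinted genes (1 over the list alone). In the bile acid list of 17, Nr0b2 (0.85) rose and Abcc3 (-0.56) fell by either adjustment. Pck1, a gene of gluconeogenesis (-0.49), was the 1 of 17 glucose metabolism genes to fall by either adjustment, and Mthfd1, an enzyme of folate metabolism (-0.41), fell among 16 methyl donor and DNA methylation genes (2 over the list alone). The calls of Akr7a3, Cd14, Fabp4, Gsr, Hlf, Nfil3, Pck1, Psmb8, Socs3 and Vsig4 were lost in at least 1 fit with an array left out, and after quantile normalization the adjusted p was 0.0619 for Akr7a3, 0.113 for Gsr and 0.073 for Socs3. Without arrays 21, 22, 24 and 25 the adjusted p was 0.0790 for Akr7a3, 0.0514 for Cd14, 0.136 for Cpa1, 0.102 for Nfil3, 0.0780 for Rgs5, 0.0996 for Socs3 and 0.0990 for Vsig4.

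Among marker lists in the average, Epcam (-0.55) was the 1 of 8 cholangiocyte markers to fall and Cpa1 the 1 of 9 pancreatic acinar markers, by either adjustment. Rgs5 (0.57, a call lost in at least 1 fit with an array left out) rose among 9 stellate cell markers, with Pdgfra (-0.28) falling over the list alone. Over all probe sets 0 members passed in limma in the lists of lymphocyte, neutrophil, endothelial, erythroid, skeletal muscle and hepatocyte markers, extracellular matrix, lipoproteins, cell cycle, oxidative phosphorylation, female-biased and male-biased genes, and 0 passed over the list alone. Of these, the hepatocyte and lymphocyte lists had camera calls that gave adjusted p = 0.71 with an estimated correlation, the cell cycle list one that gave adjusted p = 0.529 with an estimated correlation, and the male-biased list (median 0.30) one that gave adjusted p = 0.206 with an estimated correlation. The counts were also 0 over all probe sets for heat shock proteins, the unfolded protein response and amino acid catabolism, where over the list alone Dnajb1 (-0.31) and Hspb1 (-0.58), Ppp1r15a (-0.44), and Aass (-0.37), Asl (-0.31) and Got1 (-0.47) fell and Tdo2 (0.21) rose. Of 7 adipocyte markers, Fabp4 rose by either adjustment and 1 fell over the list alone.

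**Figure D3:**
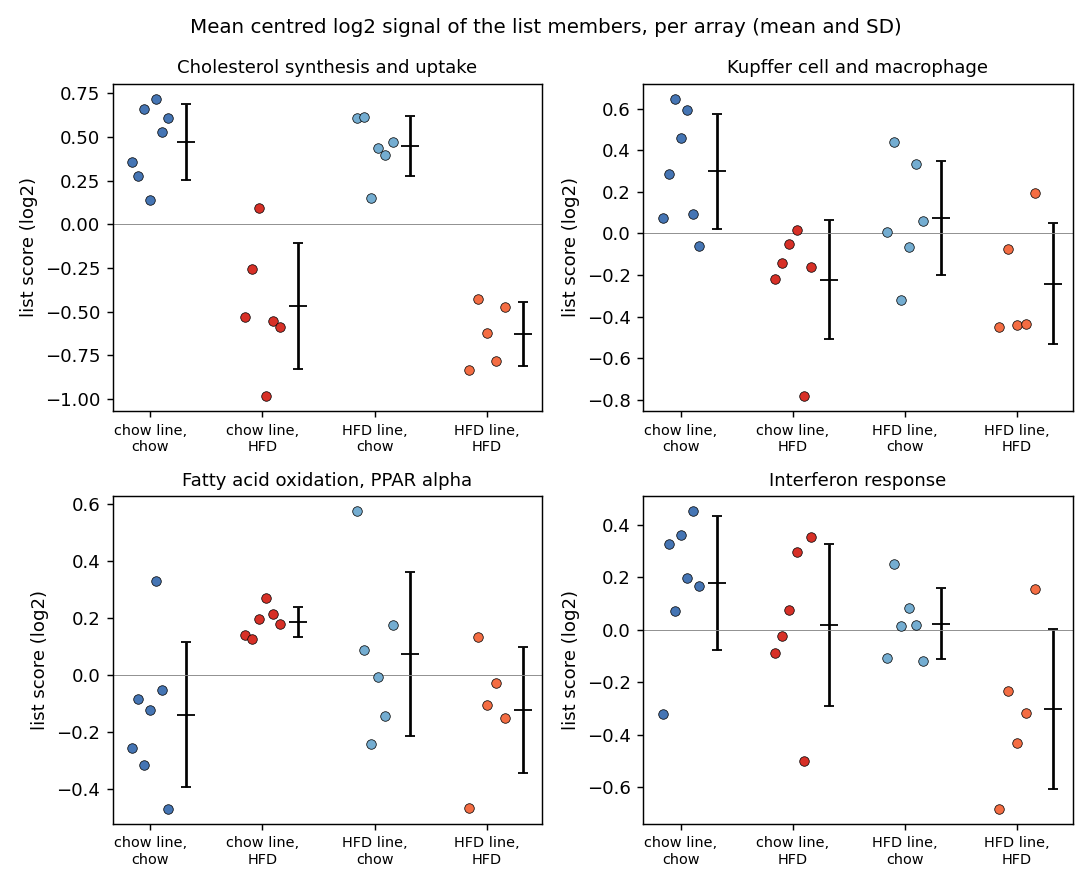
Each point is 1 array, and the vertical axis is the list score (mean log2 signal of the list's members, each centred on its mean over the 24 arrays); the bar beside each group is the mean with the SD. In the cholesterol list the means were 0.47 and -0.47 on chow and HFD in the chow line, and 0.45 and -0.63 in the HFD line.

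Grandpaternal diet on chow compared 6 HFD-line with 7 chow-line females, none of which ate the HFD themselves. By limma, 0 probe sets passed the threshold in either direction. At an unadjusted p under 0.05 there were 1435 (608 higher and 827 lower in the HFD line), where 784 would arise by chance on average, and the smallest adjusted p was 0.354. Probe sets are correlated, so chance counts can lie well away from that average, and the excess was not tested. The direction at an unadjusted p under 0.05 depended on scaling, with 1043 higher and 784 lower after quantile normalization and 1503 higher and 569 lower after centring. The smallest p among lower genes was that of Ube2n, which encodes a ubiquitin-conjugating enzyme (-0.80 ± 0.16, adjusted p = 0.354), followed by Ap1s2 (-0.64) and Rnf135 (-0.61), and among higher genes those of Scamp5 (0.58), Csnk2b (0.47) and Tcf7l1 (0.67), each with an adjusted p of 0.437. The confidence intervals (95%) had a median half-width of 0.22, and 98.7% of them lay within ±1.

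Between the lines on chow, 12 lists passed camera and 0 held with an estimated correlation. The 24 fatty acid oxidation genes had a median of 0.20, with 21 higher in the HFD line, for example Decr1 (0.48 ± 0.16), Eci1 (0.63 ± 0.22) and Vnn1 (0.73 ± 0.29), and 0 passing over the list alone (adjusted p = 0.665 with an estimated correlation). The 31 oxidative phosphorylation genes had a median of 0.13 (Cox4i1 at 0.33 ± 0.12) and the 14 macrophage markers one of -0.18 (Folr2 at -0.51 ± 0.18), with adjusted p = 0.665 with an estimated correlation for either list. Adjusted over the list alone, the cytochrome gene Cyp3a23-3a1 (1.15), the bile acid and fatty acid ligase gene Slc27a5 (0.39) and the muscle myosin gene Myh2 (0.33) were higher in the HFD line. The cholesterol list had a median of 0.00. The score of 5 neutrophil markers was lower by -0.17 (exact permutation p = 0.00117, adjusted p = 0.0396, and 0.192 after centring), with Fcnb at -0.36 ± 0.13 and 0 members passing over the list alone.

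Grandpaternal diet on the HFD compared 5 HFD-line with 6 chow-line females. The HFD-line arrays were dimmer, with a median log2 fold change over all probe sets of -0.10 that became -0.02 after centring and -0.0015 after quantile normalization. By limma 0 probe sets passed, with 1722 at an unadjusted p under 0.05 (54 higher and 1668 lower), and the smallest adjusted p was 0.175. After centring, 372 were higher and 501 lower at an unadjusted p under 0.05, and 0 passed. Relative to the median of all probe sets, the genes on the naming rule were at 0.57 for St6galnac3, 0.37 for Cd160, 0.35 for Stap1, -0.33 for Fam181b, -0.38 for Cox6c-ps1 and -0.60 for Fam13a, with adjusted p of 0.279 to 0.423 for the unshifted values. Confidence intervals (95%) had a median half-width of 0.24, and 98.4% lay within ±1.

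Between the lines on the HFD, 9 lists passed camera and 0 held with an estimated correlation. The interferon list had a median of -0.23 relative to all probe sets, and Rtp4 was the 1 of its 23 members that was lower over the list alone (-0.77 relative to all probe sets; Ifit3 was at -0.29 and did not pass), with adjusted p = 0.967 with an estimated correlation. The fatty acid oxidation list had a median of -0.14 relative to all probe sets, with Vnn1 at -0.72 and Acot1 at -0.33, 0 passing over the list alone and adjusted p = 0.967 with an estimated correlation. Over the list alone, Cyp2a1 and Cyp2c7 of the female-biased genes (-0.16 and -0.09 relative to all probe sets), Cyp3a18 and Cyp2a2 of the male-biased genes (-0.82 and -0.17) and Cpa1 of the acinar markers (-1.53) were lower. These calls over the list alone, that of Rtp4 included, were made on the unshifted fold changes (-0.26, -0.19, -0.92, -0.27 and -1.64 in the order above, and -0.87 for Rtp4), and the values relative to all probe sets were not tested. The cholesterol list lay at -0.02 relative to all probe sets.

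Averaged over own diets, grandpaternal diet also gave 0 probe sets by limma, with 1728 at an unadjusted p under 0.05 (89 higher and 1639 lower) and a smallest adjusted p of 0.061. After quantile normalization 825 were higher and 747 lower. The smallest p was that of Samd9l, an interferon-inducible gene, at -0.66 ± 0.13 (adjusted p = 0.061), followed by Minar1 (-0.41 ± 0.08, adjusted p = 0.0908) and Cox6c-ps1 (-0.35 ± 0.07, adjusted p = 0.116). Slc66a2 (0.34, adjusted p = 0.27), Bri3 (0.36) and Zdhhc4 (0.24) had the smallest p among higher genes. Samd9l passed with array weights (adjusted p = 0.00197) and without array 34 (adjusted p = 0.000642), among other settings. It did not pass with quantile normalization (adjusted p = 0.104), after centring (adjusted p = 0.145) or with the array-set block (adjusted p = 0.081). Without arrays 21, 22, 24 and 25 its adjusted p was 0.242. With array weights 54 probe sets passed, all lower in the HFD line, and without array 34 the count was 7. With the robust option it was 4. After quantile normalization and after centring 0 passed. After centring, 713 were higher and 601 lower at an unadjusted p under 0.05. The interferon response list was the 1 list that passed camera (adjusted p = 2.72e-05), with a median of -0.28 and 22 of 23 genes lower in the HFD line, but it gave adjusted p = 0.801 with an estimated correlation. Of its members 0 passed over all probe sets; over the list alone 8 were lower, with Oas1a (-0.84), Rig1 (-0.25), Ifit3 (-0.28) and Oasl (-0.50) the first by p, and Ifit1 (1.22, named after its value was seen) was higher. The list score differed by -0.24 (permutation p = 0.0418, adjusted p = 0.279). As deposited, its mean was 0.18 in the chow line and 0.02 in the HFD line on chow, and 0.02 and -0.30 on the HFD. After centring, the means lay closer together, at 0.16 and 0.00025 on chow and -0.01 and -0.20 on the HFD.

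Other members passed over the list alone in that average. Sox9 (-0.25), Cd24 (-0.39) and Krt19 (-0.32) were lower among 8 cholangiocyte markers, with a camera adjusted p of 0.148. Ier2 (-0.34), Ier3 (-0.36) and Dusp1 (-0.23) were lower among 13 immediate early genes, and Phlda2 (-0.26), the chemokine gene Ccl2 (-0.61) and Cpa1 (-1.10) were each the 1 member of their list to be lower. These calls, and those of the interferon genes above, used unshifted fold changes. The median over all probe sets in this contrast was -0.05. The acinar marker score differed by -0.20 (permutation p = 0.00137, adjusted p = 0.0466, and 0.558 after centring). The confidence intervals (95%) had a median half-width of 0.16, and 99.6% lay within ±1.

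The interaction asked whether the response to the HFD differed between the lines. By limma 0 probe sets passed, with 1523 at an unadjusted p under 0.05 (234 higher and 1289 lower) and a smallest adjusted p of 0.131. After quantile normalization 477 were higher and 569 lower. Rpa3, a subunit of replication protein A (-0.84 ± 0.18), Rpl21 (-0.48 ± 0.10) and Fam181b (-0.55 ± 0.13) shared that value, and Rnf135 (0.86 ± 0.22, adjusted p = 0.174), Scd2, a fatty acid desaturase (2.54 ± 0.75, adjusted p = 0.267), and 4930488N24Rikl (2.41 ± 0.72, adjusted p = 0.267) led the positive side. Without array 28 the count was 57, and without array 22 it was 48. Confidence intervals (95%) had a median half-width of 0.33, and 96.4% lay within ±1.

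Of the 34 lists, 7 passed camera for the interaction and 0 with an estimated correlation. All 24 fatty acid oxidation genes had a more negative response in the HFD line (median -0.47, and -0.36 after quantile normalization), and 5 passed over the list alone, among them Vnn1 (-1.55 ± 0.43), Eci1 (-1.06 ± 0.32), Decr1 (-0.77 ± 0.23) and Slc25a20, the mitochondrial carnitine carrier (-0.60 ± 0.19); the list gave adjusted p = 0.58 with an estimated correlation. The 31 oxidative phosphorylation genes had a median of -0.28 (-0.11 after quantile normalization), with Ndufs3 (-0.59) and Cox7a2 (-0.59) passing over the list alone (adjusted p = 0.58 with an estimated correlation). In the xenobiotic list (median -0.31), 5 of 22 passed over the list alone, including Cyp2a1 (-0.32), the nuclear receptor gene Nr1i3 (-0.82) and Cyp3a23-3a1 (-1.41), with adjusted p = 0.58 with an estimated correlation. The female-biased list had Cyp2a1 (-0.32) and Cyp2c7 (-0.28) passing over the list alone (adjusted p = 0.58 with an estimated correlation). The median interaction over all probe sets was -0.10. After centring, the mean female-biased score went from -0.09 on chow to 0.08 on the HFD in the chow line. In the HFD line it went from -0.01 to 0.04. As deposited, it went from -0.06 to 0.12 and from 0.01 to -0.06. The centred xenobiotic score went from -0.07 to 0.04 in the chow line and from 0.08 to -0.05 in the HFD line. As deposited, that score went from -0.05 to 0.07 and from 0.11 to -0.15. Hepatocyte markers had a median of -0.20 that became 0.0015 after quantile normalization, with Alb at -0.21 ± 0.08 and Apoh at -0.27 ± 0.10, and lymphocyte markers one of 0.17 (Gzmb at 0.26 ± 0.15); they gave adjusted p = 0.683 and 0.58 with an estimated correlation. Ccnd1 (-0.98) and Gadd45b (-1.35) passed over the cell cycle and immediate early lists alone. Macrophage markers had a median of 0.22 (C1qb at 0.39 ± 0.24) and 0 passing over the list alone (adjusted p = 0.59 with an estimated correlation), and the cholesterol list had a median of -0.12 that became 0.07 after quantile normalization, with 0 passing.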

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

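The tests of chance splits of the arrays, of array brightness for all 3 patterns, of a lower share of all non-hepatocyte cells (with each set of markers compared), and of chance over 34 lists were chosen only after the result was seen. In 100 splits of the same arrays, the real one included, chance can be excluded for the counts of probe sets changed by own diet in the chow line (1 split as large, 50 real against a highest other of 21), in the HFD line (1 split, 118 against 6) and in the average (1 split, 312 against 2). Where the real count was 0, all 100 splits are as large by construction, so they decide nothing about chance; the highest other counts were 1 for grandpaternal diet on chow, 4 on the HFD, 5 averaged and 11 for the interaction. For numbers of gene lists passing camera, chance cannot be excluded in any contrast: own diet in the chow line (13 splits as large, 12 real, highest other 18), in the HFD line (33, 11 real, highest other 16) and averaged (32, 10 real, highest other 16), grandpaternal diet on chow (7, 12 real, highest other 17), on the HFD (37, 9 real, highest other 16) and averaged (98, 1 real, highest other 16), and the interaction (58, 7 real, highest other 16).

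On the HFD, 96.9% of the probe sets at an unadjusted p under 0.05 were lower in the HFD line than in the chow line. After centring each array on its median 57.388% were lower, but centring by itself pulls the share towards balance, so this value decides nothing about array brightness as the source. The set of 4 arrays that stood apart was excluded as its source, since 95.915% were lower without them. All 5 HFD-line arrays were dimmer than the chow-line mean. Array brightness, from labelling or scanning, and a lowering of many genes by the grandpaternal diet both stay open.

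The macrophage markers were lower on the HFD in the chow line, with a score difference of -0.52 (exact permutation p = 0.0035, adjusted p = 0.0396) and 6 of 6 HFD arrays below the chow mean. Array 34 was the lowest of these, at -0.78 against -0.22 to 0.02 in the others. The score tests were not repeated without it. Array brightness was excluded, as the list median was -0.42642 after centring, and so was the array set, with -0.43841 when it entered as a block. In the chow line, the scores argued against a lower share of all non-hepatocyte cells alike. Relative to endothelial and stellate markers the macrophage score fell by 0.50338 (exact permutation p = 0.0011655). Relative to these with lymphocyte, neutrophil and cholangiocyte markers it fell by 0.452 (exact permutation p = 0.000583, the smallest possible). From chow to HFD, the endothelial score itself moved from 0.02 to -7.7e-05 and the stellate score from 0.08 to 0.06. The comparison with those 2 lists therefore largely restates the macrophage fall and is no independent test. Lymphocyte markers were lower too (score difference -0.24, exact permutation p = 0.0379, adjusted p = 0.184, 6 of 6 arrays below the chow mean), though the macrophage score fell by 0.282 relative to them (exact permutation p = 0.0035). In the HFD line the differences were -0.338 (exact permutation p = 0.0823) against endothelial and stellate markers, -0.291 (exact permutation p = 0.108) against all 5 lists and -0.237 (exact permutation p = 0.0736) against lymphocyte markers. A lower share of all these cells therefore stays open in that line. Fewer Kupffer cells, fewer immune cells of several kinds and lower expression per cell all stay open, as does a biological effect of the diet.

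The fatty acid oxidation list responded to the HFD differently in the lines, with a score interaction of -0.52229 (permutation p = 0.0057399). In the chow line 6 of 6 HFD arrays were above the chow mean, and in the HFD line 4 of 5 were below. Chance assignment of arrays to lines was excluded for this list alone, but not among 34 lists tested (adjusted p = 0.13926), so the pattern could be a chance result among the lists. Array brightness alone (-0.39344 after centring, permutation p = 0.01643) and the array set alone (-0.43338 without its 4 arrays, permutation p = 0.03058) did not account for all of the interaction. Each step made it smaller, and both together left -0.34 (permutation p = 0.053). A source in brightness and array set together was therefore not excluded. These p-values were not adjusted over the 34 lists. Hepatocyte markers moved the same way, with a score interaction of -0.19 (permutation p = 0.0164, adjusted p = 0.139) and 6 of 6 HFD arrays above the chow mean in the chow line against 2 of 5 in the HFD line. After centring their interaction was -0.06 (permutation p = 0.473). The macrophage score interaction had the opposite sign (0.20, permutation p = 0.389). Whether a different share of hepatocyte RNA lay behind the pattern was not tested, so it stays open, as does a biological effect of the grandpaternal diet on this list.

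Camera gave 7 lists for the interaction, none of which held with an estimated correlation: fatty acid oxidation (adjusted p = 2.6706e-07), oxidative phosphorylation (adjusted p = 3.2544e-07), macrophage markers (adjusted p = 3.9047e-05), lymphocyte markers (adjusted p = 0.00029709), hepatocyte markers (adjusted p = 0.0027979), xenobiotic metabolism (adjusted p = 0.0051996) and female-biased genes (adjusted p = 0.01461).

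Single arrays lay apart from their group, by the gap to the nearest array divided by the range (Dixon's ratio), in 16 of 244 groups tested, where chance picks about 1 in 20 (12.2). Higher than the rest were Vnn1 in array 34 (0.70149; 9.97 against 9.24 to 9.46), C16h10orf71 in array 30 (0.61941), Zfp354a in array 38 (0.65751), Or51r1 in array 31 (0.7162), Cox6c-ps1 in array 25 (0.66651) and Per2 in array 30 (0.66619). Lower than the rest were Kcnma1 in array 45 (0.78077, 7.47 against 8.60 to 8.92), Aacs in array 42 (0.66232), Sqle in array 39 (0.706), Tsc22d1 in array 41 (0.8719), Msmo1 in array 27 (0.59799), Tcf7l1 in array 24 (0.77661), Rnf135 in array 44 (0.75413), Cd160 in array 38 (0.66852), Zdhhc4 in array 21 (0.69758) and the macrophage list score in array 34 (0.70592, -0.78 against -0.22 to 0.02). No array was left out for these.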

How the results depend on the processing

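The array-set block, the removal of its 4 arrays, and the block with quantile normalization were chosen only after the result was seen. No paired analysis was possible because array numbers are not shared between groups. Of 102 named gene results past the threshold, 95 remained with quantile normalization, 102 with the block, 97 with both, 80 without arrays 21, 22, 24 and 25, and 68 under every removal of 1 array. The sign of Tf in the chow line turned with quantile normalization (-0.010375, and -0.011182 with the block), and that of Vnn1 in the HFD line without array 39 (-0.11657), 44 (-0.076118) or 46 (-0.027317), within a range of -0.11657 to 0.39486. Probe sets past the threshold for own diet in the chow line were 89 (quantile), 79 (centred), 95 (array weights) and 163 (quantile with block), and 34 to 56 with 1 array left out. In the HFD line they were 186 (weights), 62 (without 21, 22 and 24) and 77 (without the 4 arrays), and 56 to 148 with 1 left out (37 gave 65, 42 gave 56, 24 gave 69, 44 gave 72, 45 gave 58). Averaged they were 581 (weights) and 646 (quantile with block), and 214 to 470 with 1 left out (470 without 21). Grandpaternal diet gave on chow 1 (quantile), 3 (quantile with block) and 0 to 1 with 1 left out (1 without 41), on the HFD 0 to 4 (4 without 34, 1 without 22 or 33), and averaged 4 (lowest 50% left out), 4 (robust), 54 (weights), 2 (without 21, 22 and 24), 2 (block), 2 (without the 4 arrays) and 0 to 7 (7 without 34, 3 without 30, 1 without 21 or 22). Averaged, it gave 0 with quantile normalization and 0 after centring. The interaction gave 0 to 57 (57 without 28, 48 without 22). The correlation of the lines' own-diet effects was 0.221 to 0.360 with 1 left out (jackknife standard error 0.185). The cause was not tested.

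Lists past camera with an estimated correlation numbered 1 (own diet, chow line), 1 (HFD line), 1 (averaged), 0 (grandpaternal diet on chow), 0 (on the HFD), 0 (averaged) and 0 (interaction). Own diet in the chow line gave 10 to 13 lists with 1 array left out and the average 8 to 13. In the HFD line it gave 4 (quantile), 3 (without 21, 22 and 24), 5 (block), 3 (without the 4 arrays), 1 (quantile with block) and 3 to 18 (18 without 39, 7 without 27, 30 or 32, 6 without 38 or 47, 5 without 40, 3 without 24). Grandpaternal diet gave on chow 5 (quantile), 6 (quantile with block) and 6 to 14 (6 without 38), on the HFD 4 (quantile), 3 (centred), 2 (weights), 1 (quantile with block) and 4 to 11 (4 without 24, 34 or 47, 5 without 35), and averaged 5 (weights), 5 (without 21, 22 and 24), 5 (without the 4 arrays) and 1 to 4 (4 without 42 or 45, 3 without 32, 34 or 47, 2 without 30, 31, 39, 24 or 46). The interaction gave 7 to 12 (12 without 26, 39 or 40, 11 without 30, 41, 44 or 45).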

Other observations

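Only values are described here, for a set chosen after the result was seen, and no tests were made on it. Of the tested probe sets, 56 had a log2 fold change on the HFD under -0.4 in the chow line and over 0.4 in the HFD line, while 6 had the opposite arrangement. Of the 56, 25 had 1 gene name, with Smokxl2 on 9 probe sets, Dlg5l17 on 6, 4930488N24Rikl on 5, and Clxn, Dlg5l16, Nptx2, Rpl10l1 and Scd2 on 1 each; 31 had several names or none. Their mean centred log2 signal was 2.06 in array 45 (HFD line, HFD), 1.63 in array 26 (chow line, chow), 0.95 in array 27 (chow line, chow) and 0.82 in array 24 (HFD line, HFD), and -0.58 to 0.27 in the other 20 arrays. The lowest adjusted p of the interaction among these probe sets was 0.209 in limma.

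Hsd11b1 fell by 2.08 ± 0.35 on the HFD in the average of the lines (adjusted p = 0.000744), yet its spread on chow was wide, with 8.11 ± 1.25 (SD, n = 7) in the chow line and 8.38 ± 0.91 (n = 6) in the HFD line, against 6.17 ± 0.75 (n = 6) and 6.17 ± 0.68 (n = 5) on the HFD. Phlda2 was 6.72 on chow and 6.13 on the HFD in the chow line, and 6.51 and 5.82 in the HFD line. Ccnd1 was 9.56 and 10.46 in the chow line, and 10.17 and 10.09 in the HFD line.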
